A study of Homo sapiens with 4 samples.

How the data were processed

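The series holds 4 RNA-seq libraries of suspended MCF-7 and MDA-MB-231 cells, 1 for each line in hypoxia and in normoxia for 6 h. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a stranded mRNA kit. The submitters' processing notes name cutadapt 2.5, HISAT2 2.1.0 and featureCounts 1.6.3 with the GRCh38 build. The strand setting, the handling of reads that match several places and the annotation release are not given in the sources used here. The authors deposited 1 file of whole-number gene counts per library, with no normalization, per the file headers and values. Each file lists 58302 Ensembl gene IDs. Symbols were taken from a gene name table for 57532 of them. Positions and gene types came from GENCODE v29 on GRCh38, which holds 58039 of the IDs.

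Counts were scaled to CPM (library-size-scaled counts) with TMM effective library sizes in edgeR 4.0.16 under R 4.3.3. Per line, the log2 ratio of hypoxia over normoxia used a prior count of 2 and genes with a mean of at least 1 CPM over the 2 libraries. Its exact Clopper-Pearson 95% interval covers counting error only. Counts of at least 2-fold differences follow a fixed size rule and are not tests. A fold against a library at 0 counts was computed against 3 counts in that library and is a lower bound. In CPM, 3 counts equal 0.418, 0.393, 0.488 and 0.478 for the libraries labelled MCF-7 hypoxia, MCF-7 normoxia, MDA-MB-231 hypoxia and MDA-MB-231 normoxia.

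Genes over both lines were tested with edgeR's quasi-likelihood F-test with line and oxygen as terms (filterByExpr, 16097 genes, Benjamini-Hochberg threshold 0.05, 1 residual degree of freedom). The lines are the repeats of the oxygen contrast, so the spread behind the p-values is the difference between the hypoxia responses of the labelled lines. The line markers differ within each labelled line, so this is not a spread among replicates. The smallest adjusted p was 1 and the biological coefficient of variation 1.08. The mean log2 difference over the 4 libraries is the mean of the hypoxia values minus that of the normoxia values, which does not use the line labels. This difference and the count of genes ordered alike in both hypoxia libraries were added after the line markers had been seen.

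The labels give no replicate numbers, so the line was the pairing. The deviations of the libraries of 1 labelled line from the oxygen means correlated at -0.536 across genes. The line markers contradict the labels of both normoxia libraries. The groups were kept as labelled, no library was moved to another group, and the term "labelled" marks the affected comparisons.

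The 40 gene lists, the comparisons by line and over both lines, the naming rule and most alternatives were fixed before the data were examined. Some genes belong to several lists, so the lists are not independent. The HIF target list shares members with the glycolysis, oxygen sensing, angiogenic, JmjC, collagen and autophagy lists, among others. The measures and alternatives added later are stated as such where they are given. The rule takes the 12 highest and 12 lowest log2 ratios per labelled line among genes with a symbol and a mean of at least 5 CPM, the 10 genes farthest apart each way between lines, up to 10 per direction past each test, and list members as examples. A list's median is set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A second set, added after the data were seen, is matched in 10 bins of expression and 5 of the distance between the labelled lines' log2 ratios. Counts given for matched genes are the sum over members of the share of genes in the same bin. Figures were drawn with matplotlib 3.10.9, and lists were computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15.

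The test was run on simulated data for the hypoxia comparison over both lines, with 16097 genes, 100 changed 4-fold and 100 changed 16-fold. The counts were simulated from a fit with the libraries paired by line markers. Tested with that same pairing, it recovered 33% of the 4-fold and 68% of the 16-fold changes with 4 false calls. Tested with the lines as labelled, which is the main test here, it recovered 0% of both. Alternatives were DESeq2 1.42.0, limma-voom with limma 3.58.1, RLE and total-count scaling, prior counts of 0.5 and 5, other filters on low counts, no block, and each library left out. Mitochondrial genes held 27.8, 26.8, 26.4 and 30.2% of counts and processed pseudogenes 11.0, 10.9, 9.78 and 10.2%, in the order of libraries above. Genes with near-identical copies, such as GAPDH, and antisense genes are therefore uncertain.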

Results

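Messenger RNA was sequenced from suspended cells of 2 breast cancer lines, MCF-7, a luminal A line that expresses the estrogen receptor, and MDA-MB-231, a basal-like line with mesenchymal features. Cells in wells that prevent attachment were kept for 6 h in a sealed jar with an oxygen absorber (hypoxia) or in the ordinary incubator atmosphere (normoxia). Each of the 4 combinations of line and oxygen had 1 library. The deposited gene counts summed to 7419722 in the library labelled MCF-7 hypoxia and 7535019 in that labelled MCF-7 normoxia. They summed to 6115017 in the library labelled MDA-MB-231 hypoxia and 6362291 in that labelled MDA-MB-231 normoxia. Genes with a count numbered 19947 and 19857 in the hypoxia libraries and 22526 and 22773 in the normoxia libraries, in the same order of lines. With 1 library per group there was no replicate check of any difference within a line. Intervals cover counting error only, and all levels are CPM (the share of a library's counts, on a scale common to all libraries) after TMM scaling.

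Marker genes of the lines, fixed before the data were examined, went against the line labels of both normoxia libraries. ESR1, the estrogen receptor (ENSG00000091831, GRCh38 chromosome 6, 151656691 to 152129619), had 1239 counts in the library labelled MCF-7 hypoxia and 0 in that labelled MCF-7 normoxia, where 3 counts correspond to 0.393 CPM. It had 6 counts in the library labelled MDA-MB-231 hypoxia and 740 in that labelled MDA-MB-231 normoxia. VIM, which encodes the mesenchymal filament protein vimentin (ENSG00000026025, chromosome 10, 17228259 to 17237593), was at 20.9 and 2136 CPM in the libraries labelled MCF-7 hypoxia and normoxia, and at 1828 and 3.50 CPM in those labelled MDA-MB-231. The luminal transcription factor gene GATA3 was at 518 and 4.71 CPM in the labelled MCF-7 libraries and at 0.488 and 284 CPM in the labelled MDA-MB-231 libraries. CDH1, which encodes E-cadherin, was at 423, 2.23, 1.30 and 365 CPM in the same order. In the libraries labelled hypoxia the markers matched the line labels. Across 17583 genes, the Spearman correlation of the library labelled MCF-7 normoxia was 0.915 with MDA-MB-231 hypoxia and 0.777 with MCF-7 hypoxia. That of the library labelled MDA-MB-231 normoxia was 0.879 with MCF-7 hypoxia and 0.716 with MDA-MB-231 hypoxia. Every direction given below for a labelled line, or between labelled lines, rests on these labels. Where libraries are re-paired by line markers, MCF-7 and MDA-MB-231 name the lines by their markers. The mean difference between hypoxia and normoxia over the 4 libraries depends on the oxygen labels and not on the line labels.

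**Figure D1:**
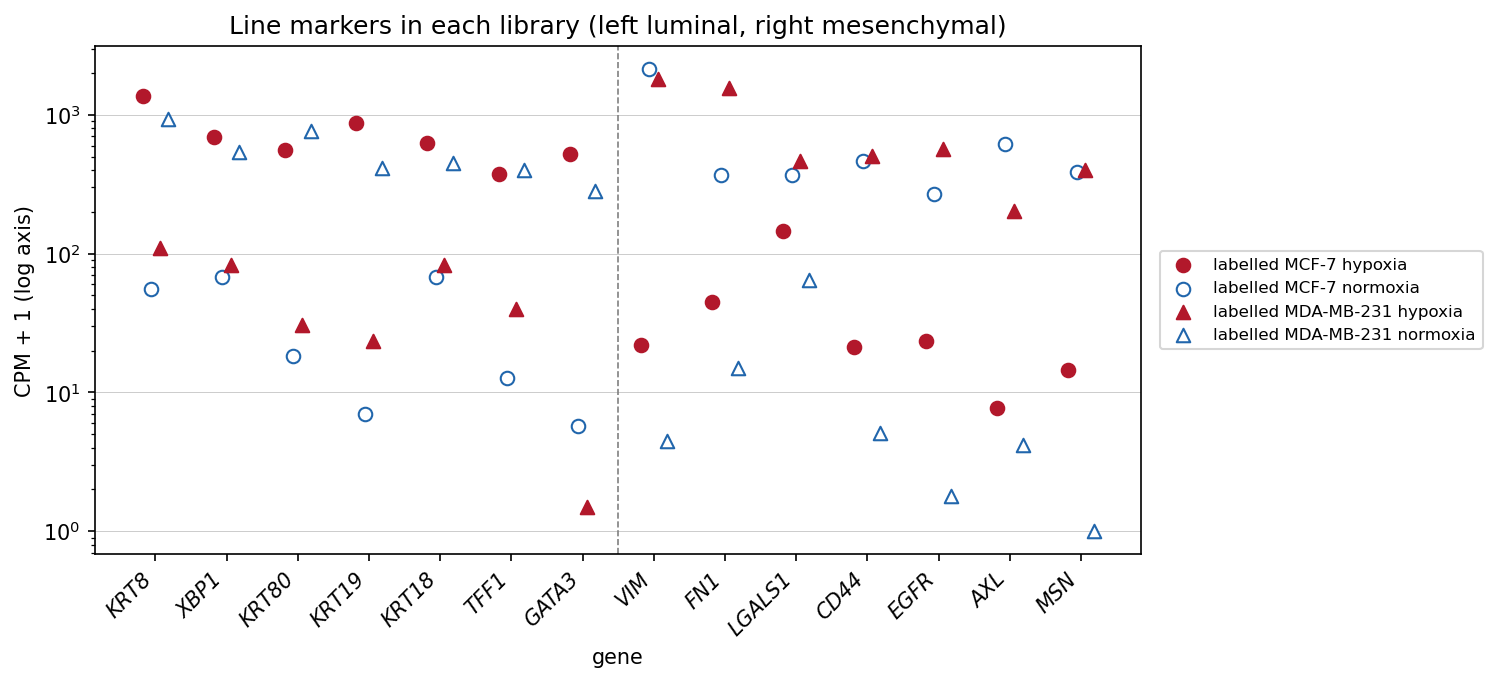
Level of the 7 most abundant measured genes of each marker list (CPM + 1, log axis) in each of the 4 libraries, 1 point per library, filled for hypoxia and open for normoxia, circles for labelled MCF-7 and triangles for labelled MDA-MB-231. The luminal genes are high in the libraries labelled MCF-7 hypoxia and MDA-MB-231 normoxia, with GATA3 at 518 and 284 CPM, and the mesenchymal genes in the other libraries, with VIM at 2136 and 1828 CPM.

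The effect of hypoxia common to both lines was taken as the difference between the hypoxia and normoxia libraries. Genes known as targets of the hypoxia-inducible factors (HIF) were higher in hypoxia as a group. The 40 measured members had a median log2 difference of 1.59, at percentile 100 of 10000 random lists matched on expression. At least 2-fold higher mean levels were found for 31 members, and 25 were higher in both hypoxia libraries than in either normoxia library, against 0 lower in both. Over all 17583 genes 1700 (9.67%) were higher and 2129 (12.1%) lower in both hypoxia libraries. Chance places 16.7% of genes in each such order only if the 4 libraries are exchangeable. These formed 2 close pairs of 1 hypoxia and 1 normoxia library, so 16.7% is no reference for genes that differ between the pairs. From the fifth of genes with the closest to the fifth with the most distant ratios in the labelled lines, the share higher fell from 21.5 to 0.51% and the share lower from 26.2 to 0.17%. Genes matched to the HIF targets on expression and on this distance would give 1.99 members higher and 1.78 lower.

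VEGFA, which encodes the main angiogenic growth factor (ENSG00000112715, chromosome 6, 43770184 to 43786487), was at 260 and 541 CPM in the hypoxia libraries labelled MCF-7 and MDA-MB-231, and at 92.2 and 60.3 CPM in the normoxia libraries. Its edgeR log2 fold change over both labelled lines was 2.33 ± 0.84 (SE). Here and below, the SE is the absolute log2 fold change divided by the square root of the F statistic. It comes from the test with lines as labelled, which no gene passed. BNIP3, which encodes a mitophagy receptor (ENSG00000176171, chromosome 10, 131966455 to 131982013), was at 179 and 175 CPM in hypoxia and 38.0 and 24.2 CPM in normoxia, a log2 fold change of 2.55 ± 0.75. Pseudogenes of BNIP3 are counted separately in the files, and the handling of reads that match several genes is not given in the sources used here. The processed pseudogene BNIP3P1 was at 282 and 248 CPM in hypoxia and 63.5 and 60.0 CPM in normoxia, above BNIP3 in each library. The level of BNIP3 itself is therefore uncertain. ANGPTL4, encoding a secreted inhibitor of lipoprotein lipase, had 306 and 834 counts in hypoxia and 84 and 12 counts in normoxia (3.997 ± 1.51). PPFIA4 was at 42.8 and 21.3 CPM in hypoxia and 2.09 and 3.34 CPM in normoxia (3.50 ± 1.17). HILPDA, which encodes a lipid droplet protein, was at 189 and 97.8 CPM in hypoxia and 11.5 and 58.7 CPM in normoxia. The list was not uniform. CA9 was above 1 CPM in the library labelled MDA-MB-231 hypoxia alone (13.7 CPM), and STC2 was at 104 and 0 CPM in hypoxia and 2.49 and 23.4 CPM in normoxia. NDRG1 was at 73.3 and 1225 CPM in hypoxia and 161 and 14.3 CPM in normoxia, so that its ranges overlapped. Paired by line markers, an alternative chosen after the data were seen, its log2 ratios were 2.33 in MCF-7 and 2.92 in MDA-MB-231.

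**Figure D2:**
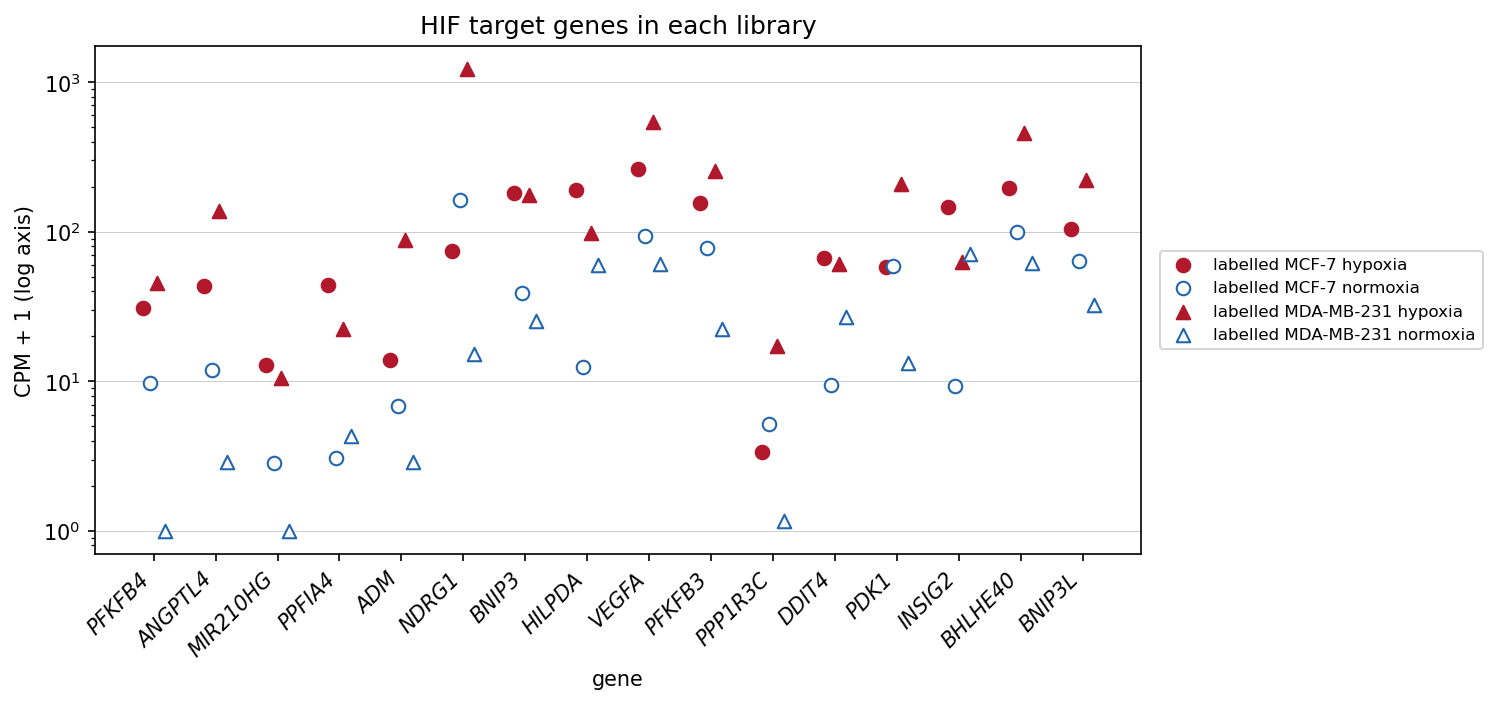
Level of the 16 HIF target genes with the highest mean log2 difference between hypoxia and normoxia and a mean of at least 5 CPM (CPM + 1, log axis), 1 point per library, filled for hypoxia and open for normoxia, circles for labelled MCF-7 and triangles for labelled MDA-MB-231. In 12 of the 16 genes both hypoxia points lie above both normoxia points.

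Glycolysis genes were also higher as a group, with a median log2 difference of 0.68 over 21 members (percentile 100). Of these, 9 were higher in both hypoxia libraries than in either normoxia library and 0 were lower in both. SLC2A1, the glucose transporter GLUT1, was at 558 and 488 CPM in hypoxia and 176 and 225 CPM in normoxia (log2 fold change 1.39 ± 0.69). HK2, a hexokinase, was at 153 and 178 CPM in hypoxia and 89.6 and 64.8 CPM in normoxia. PGK1 was at 310 and 516 CPM in hypoxia and 233 and 94.1 CPM in normoxia. LDHA, encoding lactate dehydrogenase A, was at 556 and 1485 CPM in hypoxia and 761 and 291 CPM in normoxia, so that its ranges overlapped. Paired by line markers, an alternative chosen after the data were seen, LDHA was higher in hypoxia in both pairs (556 against 291 CPM and 1485 against 761 CPM).

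Genes of the oxygen-dependent JmjC histone demethylases had a median log2 difference of 0.71 over 16 members (percentile 100), and 10 were higher in both hypoxia libraries. KDM3A was at 145 and 204 CPM in hypoxia and 81.3 and 67.3 CPM in normoxia, and KDM5C at 73.0 and 112 CPM in hypoxia and 52.1 and 48.7 CPM in normoxia. HIF subunits and oxygen sensors had a median of 0.91 over 11 members (percentile 100), with -0.27 in labelled MCF-7 and 1.94 in labelled MDA-MB-231. Of these genes 3 were higher and 0 lower in both hypoxia libraries. In that list CITED2, a HIF antagonist, was at 222 and 80.0 CPM in hypoxia and 15.6 and 38.0 CPM in normoxia. Collagen hydroxylation and crosslinking genes had a median of 0.90 over 14 members (percentile 100), with -0.91 over 11 members in labelled MCF-7 and 2.29 over 14 in labelled MDA-MB-231. In both hypoxia libraries 3 of the 14 were higher and 1 was lower, and the labelled medians give no common direction for this list or the previous one. Paired by line markers, an alternative chosen after the data were seen, the medians in MCF-7 and MDA-MB-231 were 0.59 (percentile 99.1) and 0.90 (percentile 99.96) for HIF subunits, and 0.26 (percentile 85.2) and 0.92 (percentile 99.98) for collagen genes. P4HA1 was at 129 and 106 CPM in hypoxia and 63.8 and 26.6 CPM in normoxia. PLOD2 in that list was at 126 and 280 CPM in hypoxia and 109 and 57.0 CPM in normoxia. The HIF target list also holds KDM3A, KDM4B, EGLN1, EGLN3, P4HA1, P4HA2 and LOX, so these groups share members with it.

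Genes of the integrated stress response had a median log2 difference of -0.99 over 18 members (percentile 0), 9 of them at least 2-fold lower and 1 at least 2-fold higher. Only 3 members were lower in both hypoxia libraries, against 0.92 for matched genes, and 1 was higher in both. The medians were 0.13 in labelled MCF-7 and -2.15 in labelled MDA-MB-231. With the normoxia libraries paired to the other line label, chosen after the data were seen, they were -0.74 (percentile 0.02) and -0.72 (percentile 0.19). ATF3 was at 1.53 and 1.14 CPM in hypoxia and 2.62 and 54.0 CPM in normoxia. DDIT3, which encodes the transcription factor CHOP, was at 0.418 and 2.60 CPM in hypoxia and 7.99 and 10.7 CPM in normoxia. Its 0.418 CPM equals 3 counts. ATF4 itself was at 120 and 171 CPM in hypoxia and 140 and 201 CPM in normoxia. The p53 target genes had a median of -0.42 over 24 members (percentile 0.43), with -0.08 in labelled MCF-7 and -1.37 in labelled MDA-MB-231. Of these genes 4 were lower in both hypoxia libraries, against 2.48 for matched genes, among them PLK2 at 24.7 and 19.5 CPM in hypoxia and 27.1 and 158 CPM in normoxia. DNA replication genes had a median of -0.22 over 25 members (percentile 1.94). The medians were 0.10 in labelled MCF-7 and -0.59 in labelled MDA-MB-231. With the re-pairing they were 0.28 (percentile 97.2) and -0.86 (percentile 0), so no common direction is given. Of the 25 genes, 7 were lower in both hypoxia libraries, against 2.97 for matched genes. Examples were TYMS (40.8 and 24.9 CPM against 93.7 and 46.5 CPM) and UHRF1 (32.3 and 11.7 CPM against 65.5 and 35.3 CPM).

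No gene passed the test over both labelled lines. The edgeR quasi-likelihood test of 16097 genes, with line as a block and 1 residual degree of freedom, called 0 genes higher and 0 lower at an adjusted p under 0.05. DESeq2 and limma-voom, with the same line term, also called 0. At an unadjusted p under 0.05 edgeR gave 10 genes, all higher in hypoxia. In counts simulated with the lines paired by markers, the edgeR test with lines as labelled recovered 0% of 4-fold and 16-fold changes. Its 0 calls therefore do not show that hypoxia changed no gene. Adjusted over the list alone, 0 of the 39 tested HIF targets passed with the lines as labelled. The labelled lines differed strongly in their hypoxia ratios, which enter this test as its spread. With the normoxia libraries paired to the other line label, an alternative chosen after the data were seen, the same test called 13 genes higher and 0 lower, and 25 of the 39 HIF targets passed as higher and 0 as lower over the list alone. These calls depend on the method, as DESeq2 called 41 genes higher and 3 lower with that pairing and limma-voom 0. BNIP3 and its pseudogene BNIP3P1 were both among the 13, and their reads may be shared. The edgeR fit without a line term, which is the same for either pairing, called 0.

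The library labelled MCF-7 hypoxia was compared with that labelled MCF-7 normoxia, although the line markers of these libraries differ. Differences between lines are therefore not separated from a response to hypoxia. Of 16870 genes, 4161 were at least 2-fold higher and 3986 at least 2-fold lower in hypoxia. ESR1, ELF3 and RAB25 of the luminal marker list were among the 12 highest ratios. IGFBP5 (ENSG00000115461, chromosome 2, 216672105 to 216695525) had 51981 counts against 14, a log2 ratio of 11.73 (95% counting interval 11.20 to 12.82). SPTSSB had 6488 counts against 2 (10.67) and the long non-coding RNA DSCAM-AS1 had 6480 against 4 (10.11). FBP1, encoding a gluconeogenic phosphatase, had 2009 counts against 0 and was at least 713-fold higher, computed against 3 counts in the library at 0. ESR1 was at least 440-fold higher on that basis, EDN2 356-fold, ELF3 345-fold, RAB25 253-fold, QPRT 246-fold and CDYL2 241-fold. ELOVL2 (log2 ratio 9.47) and CRABP2 (8.72) completed the 12 highest.

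All 12 genes with the lowest ratios in the labelled MCF-7 comparison had at least 354 counts, the value of SERPINE1, in the library labelled MDA-MB-231 hypoxia. NT5E, which encodes the ectonucleotidase CD73, had 0 counts in hypoxia against 3929 in normoxia and was at least 1230.1-fold lower. FOSL1 (at least 616-fold lower), the pseudogene LDHBP2 (579-fold), ARHGDIB (571-fold), NRG1 (475-fold), RAC2 (395-fold), PLAU (299-fold), SERPINE1 (291-fold), CD96 (241-fold) and SERPINE2 (236-fold) likewise had 0 counts in hypoxia. BCAT1 and ITGA6 had 1 count in hypoxia, with log2 ratios of -8.67 and -8.45. The luminal marker list had a median log2 ratio of 5.09 with 22 of 23 members at least 2-fold higher, and the mesenchymal list a median of -4.61 with 23 of 25 at least 2-fold lower. HIF targets had a median of 1.02 over 39 members (percentile 100), with 20 at least 2-fold higher and 4 at least 2-fold lower. Cholesterol synthesis genes had a median of 2.33 over 24 members (percentile 100). These values come from a pair of libraries whose line markers differ. With the normoxia libraries paired to the other line label, chosen after the data were seen, NT5E had 0 counts in hypoxia and 1 in normoxia, too few for a ratio. In the library labelled MDA-MB-231 normoxia, SERPINE2, FOSL1, BCAT1 and CD96 had 120, 68, 36 and 25 counts. The other genes of the 12 lowest had at most 8 there. Re-paired log2 ratios of the 12 highest were 4.23 for EDN2, 1.46 for ELOVL2, 1.12 for IGFBP5, 1.02 for FBP1 and -0.62 for CDYL2. The others of the 12 lay from 0.03 (QPRT) to 0.75 (SPTSSB). In that pairing 2869 genes were at least 2-fold higher and 4384 lower (1085 and 1220 at a mean of at least 5 CPM). The cholesterol synthesis median was then -0.01 (percentile 21.4).

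The library labelled MDA-MB-231 hypoxia was compared with that labelled MDA-MB-231 normoxia, although the line markers of these libraries differ. Differences between lines are therefore not separated from a response to hypoxia, here and in the next paragraph. Of 18556 genes, 4542 were at least 2-fold higher and 5860 at least 2-fold lower in hypoxia. With the normoxia libraries paired to the other line label, chosen after the data were seen, 2939 of 16368 genes were higher and 2475 lower. F3, which encodes the coagulation initiator tissue factor, had 4906 counts against 1, a log2 ratio of 10.78 (95% counting interval 9.81 to 17.60). NT5E had 3826 counts against 1 (10.43), DUSP6 had 3025 against 1 (10.09), MUC5AC 2030 against 1 (9.51) and PLAU 1559 against 1 (9.13). Genes with 0 counts in normoxia were MSN (at least 836-fold higher), CDH11 (689-fold), ADGRF5 (595-fold), LDHBP2 (550-fold), RAC2 (492-fold), SLC2A3 (477-fold) and GPX1 (416-fold). MSN, LDHBP2 and GPX1 have related pseudogenes or parent genes in the files, so their counts are uncertain. With the normoxia libraries paired to the other line label, the log2 ratios of these genes split. They were 4.88 for CDH11, 3.46 for F3, 3.38 for ADGRF5, 2.46 for MUC5AC, 2.40 for DUSP6, 2.16 for SLC2A3 and 1.02 for PLAU. For RAC2, NT5E, GPX1, LDHBP2 and MSN they were 0.51, 0.27, 0.22, 0.12 and 0.05.

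The lowest ratios in the labelled MDA-MB-231 comparison were those of IGFBP5, with 4 counts against 20988 (log2 ratio -11.79), and of genes at 0 counts in hypoxia. These were DSCAM-AS1 (at least 1351-fold lower), SPTSSB (1100-fold), CRABP2 (853-fold), ELAPOR1 (344-fold), ABCA12 (322-fold), CDYL2 (297-fold), FBP1 (283-fold), GRHL2 (239-fold) and TSPYL5 (196-fold). ESRP1, an epithelial splicing regulator, and GATA3 had log2 ratios of -8.58 and -8.51. The luminal list had a median of -4.68 with 22 of 23 members at least 2-fold lower, and the mesenchymal list a median of 5.17 with 24 of 27 at least 2-fold higher. HIF targets had a median of 2.495 over 40 members (percentile 100), with 32 at least 2-fold higher and 3 at least 2-fold lower. With the normoxia libraries paired to the other line label, the HIF median was 1.84 over 39 members (percentile 100). Integrated stress response genes had a median of -2.15 over 18 members (percentile 0), against 0.13 over 17 members in the labelled MCF-7 comparison. That contrast rests on the labels, since the re-paired medians of the stress response list given above were nearly equal.

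The hypoxia log2 ratios of the labelled lines were opposed across genes, with Pearson r of -0.529 and Spearman rho of -0.462 over 17583 genes, which are not independent replicates. Genes at least 2-fold higher in both labelled lines numbered 448, against 967 for independent lists, and genes at least 2-fold lower in both numbered 674, against 1208. The ratios of 7983 genes lay at least 4-fold apart. The deficit became an excess with the normoxia libraries paired to the other line label, where 628 genes were higher in both against 407 and 814 lower in both against 568, and r was 0.0152. The genes farthest apart toward a higher ratio in labelled MDA-MB-231 were NT5E, LDHBP2, RAC2, PLAU, DUSP6, ARHGDIB, NRG1, LAPTM5, COL6A1 and MSNP1. Those farthest apart toward a higher ratio in labelled MCF-7 were IGFBP5, SPTSSB, DSCAM-AS1, CRABP2, FBP1, CDYL2, ESRP1, QPRT, RAB25 and TSPYL5. No test of the difference was possible with 1 library per group.

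The labelled lines were also compared over both oxygen conditions. In the edgeR test 0 genes were higher and 0 lower in labelled MDA-MB-231 than in labelled MCF-7 at an adjusted p under 0.05, and 8 of 16097 passed at an unadjusted p under 0.05. DESeq2 and limma-voom called 0. For the line markers, each labelled line held 1 library with high and 1 with low levels. For EPCAM, an epithelial adhesion gene, these were 177 and 2.62 CPM in labelled MCF-7 hypoxia and normoxia, and 1.95 and 150 CPM in labelled MDA-MB-231. With the normoxia libraries paired to the other line label, 972 genes were higher and 833 lower. That pairing was chosen from line markers in these same counts, so calls between lines follow in part from the choice.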

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

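The tests of exchanged labels and of mixing were chosen after the marker values had been seen, and the remaining tests in this part before their results were. The exchange test kept 17534 of the 17583 genes correlated above, and the mixing test used the same marker lists. Both therefore largely restate values given above and are not independent of them. The differences between labelled lines in the next paragraph were not tested, because each group had 1 library.

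Gene groups moved in opposite directions in the labelled lines. The median log2 ratio in labelled MDA-MB-231 minus that in labelled MCF-7 was -9.78 for luminal markers, 9.78 for mesenchymal markers, 8.79 for platelet and coagulation factors and 4.70 for regulators of the epithelial-mesenchymal transition. It was -5.04 for cholesterol synthesis, -3.51 for the estrogen receptor and its targets and 3.42 for NF-kB and inflammatory genes. In all, 4520 genes were at least 2-fold higher in one labelled line and at least 2-fold lower in the other.

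An exchange of the line labels of the normoxia libraries may account for the opposed markers, since outside the marker lists each normoxia library correlated more closely with the hypoxia library of the other line label, with a smaller gain in Spearman rho of 0.134. A change of marker expression with oxygen is argued against by 32 genes at 17q23 (chromosome 17, 59619689 to 61863521), known to be amplified in MCF-7, whose median log2 ratio of 2.04 in labelled MCF-7 lay above 100% of other blocks, and that of -3.62 in labelled MDA-MB-231 above 0%. In the pairs formed by line markers, the block was at -0.45 (percentile 2.24, just outside the central 95%) and at 0 (percentile 52.0). Mixing of cells or RNA is argued against by own-label markers, whose median level in the normoxia libraries was at most 0.0192 of that in hypoxia. The step at which an exchange happened stays open, and these tests do not address the oxygen labels.

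Both hypoxia libraries had fewer genes with a count, with a gap between means of 2748 genes. Thinning to the smallest total left a gap of 2657 and thinning outside the 100 most abundant genes left 2640.5, which argues against library size and a few dominant genes. Background reads in the normoxia libraries could contribute, as 34.7% of the 1192 genes counted in both normoxia and neither hypoxia library were protein coding, below the 51.95% of all detected genes. The prediction named a second comparator that was not met, the 335 genes counted in both hypoxia and neither normoxia library, at 29.55%. Since thinly counted genes are low in either set, background stays open beside a biological effect of oxygen, which was not tested.

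Reads shared between genes and their processed pseudogenes could blur single genes. Across 1719 pairs, the Spearman correlation of the hypoxia minus normoxia differences was 0.114, above 0.0517, the upper end of the central 95% of shuffled pairs, and below the 0.5 set in advance. Sharing of reads and joint regulation cannot be told apart from these counts.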

How the results depend on the processing

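Pairing by line markers, leaving out mitochondrial genes, the fits without a line term that leave out 1 library, the scalings of the 4-library order, and random lists matched on the distance between labelled lines were chosen after the data were seen. Unless stated, the cause was not tested. Calls over both labelled lines stayed at 0 per direction with DESeq2, limma-voom, RLE, total counts, no filter, no replicate block, and without each library in turn (0 to 0). With the line term, leaving out a library leaves no residual degrees of freedom.

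With the normoxia libraries paired to the other line label, 13 genes were higher and 0 lower in hypoxia. The higher count was 41 with DESeq2, 0 with limma-voom, 22 with RLE, 23 with total counts, 82 with no filter and 0 without the block. For lines, 972 genes were higher and 833 lower in MDA-MB-231. At least 2-fold differences numbered 2869 higher and 4384 lower in MCF-7, and 2939 higher and 2475 lower in MDA-MB-231, with 1807, 3173, 1747 and 1408 wholly beyond 2-fold by counting interval, 1085, 1220, 1243 and 1046 at 5 CPM, and 4462, 7762, 4769 and 5924 without a filter. Responses 4-fold apart numbered 4337, and genes higher and lower in both lines 628 and 814. The correlation between lines turned to 0.0152. Of 20 list medians in a labelled line 6 changed sign and 10 left their own interval, with shifts up to 5.891 log2. These 20 came from HIF targets, glycolysis, the integrated stress response, and lists with labelled medians at least 2-fold in opposite directions. All 48 named genes left their counting interval, with shifts up to 10.618 log2, and 5 changed sign. The 48 were the most extreme labelled ratios, so large shifts follow from that choice. Neither count is a rate for genes or lists in general. Over the list alone 25 of 39 HIF targets were then higher. The medians in MCF-7 and MDA-MB-231 became 0.28 and -0.86 for DNA replication, 0.60 and -0.94 for mitosis, 0.40 and -0.66 for heat shock genes, -0.74 and -0.72 for the integrated stress response, and -0.01 and -0.15 for cholesterol synthesis.

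A minimum of 5 CPM, which tests fewer genes, gave 2162 higher and 2347 lower in labelled MCF-7, 2690 and 2515 in labelled MDA-MB-231, 127 higher and 121 lower in both, 4339 responses apart and a correlation of -0.712. Without a filter, which tests more, these became 7518 lower in labelled MCF-7, 9225 lower in labelled MDA-MB-231, 1248 lower in both, 13663 apart and -0.393. Genes higher in both hypoxia libraries ranged from 1597 to 1810 with RLE, total counts or mitochondrial genes left out, and lower ones from 2030 to 2430. Of 39 list medians over the 4 libraries, 6 changed sign at 5 CPM, 2 with total counts, 1 with RLE and 0 with a prior count of 5. A prior count of 5 put 42 of 48 named genes outside their counting interval, with shifts up to 1.321 log2, and one of 0.5 put 0 outside, with shifts up to 2.0. With random lists matched also on the distance between the labelled lines' ratios, 2 of 40 lists moved into the central 95%, luminal markers at 97.3 and integrins and focal adhesion at 97.3. Depth limits genes near 3 counts.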

Other observations

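The gene lists not described above are given here as median log2 differences between hypoxia and normoxia over the 4 libraries, with percentiles among matched random lists. The marker lists and the estrogen receptor list hold genes far apart between the pairs of close libraries, and lists matched on expression alone do not match that spread. Their medians of 0.49 for mesenchymal markers (percentile 100), 0.33 for luminal markers (percentile 99.99) and 0.55 for the estrogen receptor and its targets (percentile 100) are not read as a direction. With the distance between labelled lines matched as well, these percentiles were 99.7, 97.3 and 99.96. In both hypoxia libraries 0 members of either marker list were higher and 0 lower, and in the estrogen receptor list 5 were higher and 2 lower. Further positive medians were 0.50 for autophagy and mitophagy (percentile 99.9), 0.31 for interferon-stimulated genes (percentile 98.9), 0.28 for integrins and focal adhesion (percentile 99.6), 0.21 for immune evasion and adenosine genes (percentile 94.2), 0.16 for platelet and coagulation factors (percentile 91) and 0.16 for acid-base transport (percentile 83.5). FOS, an immediate early gene, was at 3.07 and 24.1 CPM in hypoxia and 0.917 and 0.318 CPM in normoxia, whereas IER5 was at 10.6 and 24.2 CPM against 37.4 and 79.9 CPM. The 0.318 CPM of FOS lies below 3 counts, which equal 0.478 CPM in that library. The immediate early list as a whole was at -0.43 (percentile 0.02), the NRF2 targets at -0.33 (percentile 0.08) and the endoplasmic reticulum chaperones at -0.17 (percentile 4.58). The immediate early and NRF2 medians give no common direction. In labelled MCF-7 and MDA-MB-231 they were -0.45 and 0.05 for immediate early genes and 0.24 and -0.22 for NRF2 targets, and in both hypoxia libraries 3 and 2 members were higher and 4 and 2 lower. Labelled medians of opposite sign also lay behind the values above for autophagy and mitophagy (-0.38 and 0.81), interferon-stimulated genes (-0.65 and 0.82), integrins and focal adhesion (-0.99 and 2.04), platelet and coagulation factors (-5.00 and 3.79), immune evasion and adenosine genes (-0.90 and 1.74), acid-base transport (0.10 and -0.03) and endoplasmic reticulum chaperones (0.02 and -0.60).

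The remaining lists lay within the central 95% of random lists, which does not show that they did not change, since a median near 0 can average opposite moves and some move with the pairing of libraries. Mitosis genes had medians of -0.66 in labelled MCF-7 (percentile 0.14) and 0.36 in labelled MDA-MB-231 (percentile 89.6), and heat shock genes of -0.54 (percentile 1.96) and 0.01 (percentile 48.4). Pairing by line markers gave 0.60 (percentile 100) and -0.94 (percentile 0) for mitosis and 0.40 (percentile 99.2) and -0.66 (percentile 0.01) for heat shock genes, so no direction is given. Of those above 0 the medians were 0.12 for angiogenic factors (percentile 83.3), 0.09 for fatty acid synthesis (percentile 78.5), 0.07 for NF-kB genes (percentile 75), 0.07 for ribosomal proteins (percentile 79), 0.06 for long non-coding RNAs (percentile 67.6), 0.05 for nuclear respiratory chain genes (percentile 75.3), 0.02 for histone genes (percentile 62.9) and 0.01 for cholesterol synthesis (percentile 55.2). Below 0 they were -0.07 for mitochondrial mRNAs (percentile 13), -0.06 for iron handling (percentile 32.1), -0.08 for heat shock genes (percentile 16.4), -0.09 for RNA polymerase III and mitochondrial ribosomal RNAs (percentile 28.4), -0.09 for ribosome biogenesis (percentile 9.41), -0.10 for mitosis (percentile 7.13), -0.13 for the BCL2 family (percentile 28.4) and -0.17 for epithelial-mesenchymal transition regulators (percentile 13.4). They were also -0.26 for metallothioneins (percentile 16), -0.29 for stem and Notch genes (percentile 5.84), -0.35 for the circadian clock (percentile 5.9) and -0.0020 for nonsense-mediated decay and splicing factors (percentile 38.7).

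Several medians also change with the pairing of the normoxia libraries to the other line label, chosen after the data were seen, given here for MCF-7 and then MDA-MB-231. Both medians were positive for HIF targets (1.61 and 1.84, both at percentile 100), glycolysis (0.81 and 0.76, both at percentile 100), JmjC demethylases (0.27 and 1.03, percentiles 90.9 and 100), angiogenic factors (0.72 and 0.70, percentiles 99.9 and 99.8), integrins and focal adhesion (0.24 and 0.52, percentiles 92.1 and 100) and immune evasion genes (0.45 and 0.22, percentiles 97.6 and 85.9). Positive medians were also found for the estrogen receptor list (0.36 and 0.69, percentiles 98.7 and 99.8). Mesenchymal markers were at 1.28 and 0.37 (percentiles 100 and 99.9) and luminal markers at 0.21 and 0.85 (percentiles 88.5 and 99.7). The pairing was chosen from line markers, so no direction is read from these lists. Angiogenic factors had labelled medians of 0.38 and 0.32, with 4 members higher and 0 lower in both hypoxia libraries. Both re-paired medians were negative for p53 targets (-0.69 and -0.25, percentiles 0.04 and 9.22) and metallothioneins (-1.23 and -0.14, percentiles 0.05 and 32.7). Signs differed for interferon-stimulated genes (1.20 and -0.18, percentiles 100 and 17.3), NF-kB genes (-1.39 and 1.59, percentiles 0.17 and 100), NRF2 targets (-0.47 and 0.26, percentiles 0.02 and 95.3), platelet factors (-0.36 and 0.60, percentiles 24.9 and 99.99), fatty acid synthesis (-0.32 and 0.41, percentiles 3.33 and 98.6), immediate early genes (-0.17 and 0.25, percentiles 18.0 and 93.2) and autophagy (-0.14 and 0.21, percentiles 27.8 and 84.0).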
